A study of Drosophila melanogaster with 4 samples.

How the data were processed

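Two-colour arrays were used to compare polyadenylated RNA precipitated with an antibody to GFP from larvae expressing GFP-B52 and from larvae expressing GFP-NLS, both under the GMR driver. Per the labels, each pool held the front ends of 600 larvae, dissected at the anterior, and 2 replicates were each hybridised with both dye orientations, which gave 4 arrays. The labels do not say whether replicate 2 came from other larvae than replicate 1. The p-values of single probes and genes therefore measure only the spread between these samples, which may be technical. Those of camera with the preset correlation rest on the spread between genes, and the binomial and permutation p-values on counts of probes or genes. The 2 dye orientations of a replicate were not counted as separate samples, so n is 2.

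The authors deposited 1 table of log ratios of the 2 channels, a unit of another kind than counts or intensities, for 15744 probes. The log base, the direction of the ratio, the background correction and the normalization are not given in the sources used here. Medians between 0.002 and 0.006 show that the deposited columns were centred. There were 16 cells with the placeholder -10000, which were treated as missing, and between 350 and 955 empty cells per array. Intensities were not analysed here, so signal over background is unknown for every probe. The test design was written for log2 values; as the base turned out to be unstated, values are given in deposited log units.

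Names came from the platform annotation as it was supplied, matched by gene identifier to the gene table of assembly Release 6. Of all probes 13147 had exactly 1 gene symbol, 99 had several and 2498 had none here. The 12519 probes found through the gene identifier took the current symbol and 628 kept the symbol of the annotation. Positions in Release 6 are those of the genes, not of the probes.

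Each array was centred on its median. The arrays with B52 RNA in Cy5 were multiplied by -1 and those with B52 RNA in Cy3 by 1, which fits columns that hold a fixed dye ratio. This reading and the sign were chosen after the values of B52 probe 13309 were seen, at -0.45 and -0.51 with B52 RNA in Cy5 and 0.42 and 0.50 with B52 RNA in Cy3 as deposited. The columns without turning were run as an alternative. The 2 dye orientations of each replicate were then averaged.

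Probes with a value on all 4 arrays were tested in limma 3.58.1 under R 4.3.3, with lmFit and eBayes on the mean of 2 replicates against 0 and Benjamini-Hochberg adjustment at 0.05. The moderation added 3.47 prior degrees of freedom to the 1 of the replicates. A rule of size without a test counted probes at least 0.301 log units from 0 in 1 direction on all 4 arrays, the log10 of 2, which replaced the designed distance of 1, 2-fold on a log2 scale, after the data were seen. It was counted beside the same count under the sign patterns of dye, replicate and interaction. Correlations are across probes. Gene lists were tested on gene means, with probes of a gene averaged, by camera with a preset correlation of 0.01 and at least 5 measured genes. Of 28 lists 27 could be tested; the other, of B52, gl and w, had too few members. Entries of the lists without a match in the gene table numbered 10.

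The turning, the distance of the size rule, the adjustment over 1 list alone and the alternatives said to be added later were not planned. The groups, the other tests, the gene lists, the other alternatives below and the rule for named genes were chosen before the data were examined. By that rule the named genes were B52, then the 10 probes with a single gene symbol and the largest mean on each side among those past the adjusted p of 0.05 and of 1 direction on all 4 arrays, filled up by size among probes of 1 direction on all 4 arrays where fewer passed, and up to 4 members of a described list by the size of the moderated statistic. As no probe passed, all named probes were filled up by size. Genes named for the size rule, single genes that passed an alternative, the paralogs of Hsp70Ba and the neighbouring genes were chosen after their values were seen.

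The tests were checked on simulated data with 13963 probes, of which 100 were changed by 0.3 and 100 by 0.6. The test on the replicate means recovered 3 and 89 of these with 10 false calls, and the fit with a random block recovered 64 and 93 with 69 false calls. Camera with the preset correlation called 0 lists in 20 draws without a shifted list; genes were drawn independently, so this does not bear on the choice between a preset and an estimated correlation.

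The alternatives were values without centring, arrays scaled to a common median absolute deviation, at least 1 array per replicate, leaving out each replicate and each array, 4 arrays as separate samples with and without a dye term, a random block, robust moderation, genes in place of probes, no turning, other sizes, an estimated correlation, and fry. The removal of print position, the restriction to probes with a single gene symbol and genes of a single list were added after the data were seen, as was the log10 reading of the size rule. For print position, the median over a window of 5 columns and 7 rows was subtracted on each array, with 16 columns and blocks of 41 rows inferred from the order of the probes and the periodicity of their values. The planned relation of the ratios to intron number and transcript length was not run, as exon structures were not analysed here. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.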

Results

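The series asked which messenger RNAs the splicing factor B52 binds while the Drosophila eye forms. B52, also called SRp55, is an SR protein, a class of RNA-binding proteins with a domain rich in arginine and serine that helps to choose splice sites. Larvae carried GFP-B52 or, as the control, GFP with a nuclear localisation signal (GFP-NLS), each put under the GMR driver, which is active in the developing eye. Extracts from the front ends of 600 larvae of the third instar were precipitated with an antibody to GFP, and the polyadenylated RNA from both precipitates was hybridised together on two-colour arrays. There were 2 replicates, each with both dye orientations, so 4 arrays and 1 comparison. Values were present for between 14788 and 15394 of 15744 probes per array, and 13963 probes, for 11173 genes, had a value on all 4 arrays. The number of arrays limits the precision of every value.

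The deposited values are log ratios whose log base and ratio direction are not given in the sources used here. The arrays were turned so that a fixed dye ratio became a fixed ratio of the precipitates, and positive values stand for the side on which B52 probe 13309 lay. That side is called the B52-probe side, and which precipitate was higher on it stays unknown. Folds are given for both a log10 and a log2 reading.

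For the question of which RNAs differed between the precipitates, 1 of the 5 probes for B52 was among the probes farthest from 0, while the mean over all 5 was 0.08 ± 0.03 log units (SD, n = 2; adjusted p = 0.464 over genes in limma). B52 probe 13309, from whose values the turning was chosen, lay at 0.47 ± 0.05 log units (SD, n = 2), which is 2.94-fold on a log10 reading and 1.38-fold on a log2 reading, with array values between 0.41 and 0.51. On the same side lay Arc1, which encodes a capsid-forming protein of neurons, at 0.47 ± 0.01, the translation initiation factor eIF3g1 at 0.39 ± 0.004 and the ribosomal protein gene RpL36A at 0.37 ± 0.04. On the opposite side lay pen-2, a subunit of gamma-secretase, at -0.87 ± 0.01, which is 7.42-fold or 1.83-fold on the respective readings. None of these probes passed the test over all probes, in which pen-2 had the smallest adjusted p, 0.238 in limma.

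Among probes with a single gene symbol, the 10 largest values on the B52-probe side that kept 1 direction on all 4 arrays belonged, besides B52, Arc1, eIF3g1 and RpL36A, to CG15784 at 0.64 ± 0.25, the antibacterial peptide gene Listericin at 0.55 ± 0.18 and CG13561 at 0.49 ± 0.34. CG7912 at 0.44 ± 0.30, the glutathione transferase gene GstD7 at 0.42 ± 0.06 and CG7916 at 0.38 ± 0.03 completed them. CG7912 had 1 array at 1.13 and the other 3 between 0.08 and 0.38. The adjusted p of these 10 probes in limma lay between 0.268 and 0.294.

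The 10 such probes on the opposite side held 2 enzymes of catecholamine metabolism. They were speck, an arylalkylamine N-acetyltransferase, at -0.63 ± 0.09 and e (ebony), which joins beta-alanine to dopamine, at -0.60 ± 0.03. The heat-inducible chaperone gene Hsp70Ba lay at -0.62 ± 0.14, the kinetochore gene Mis12 at -0.57 ± 0.17 and the microcephalin gene MCPH1 at -0.56 ± 0.43. The antibacterial peptide gene CecB lay at -0.57 ± 0.20, the salivary gland gene ng1 at -0.54 ± 0.37, CG4151 at -0.57 ± 0.32 and CG3348 at -0.53 ± 0.11, all with n = 2. Their adjusted p in limma, with pen-2 included, lay between 0.238 and 0.3.

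**Figure D1:**
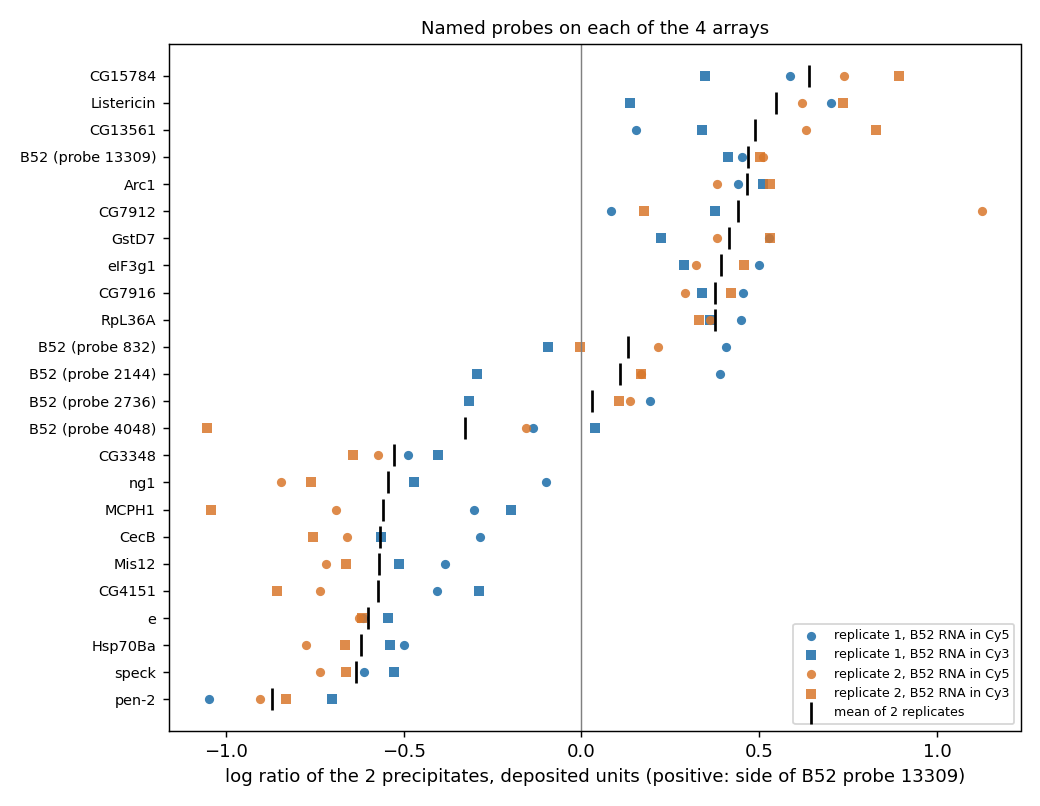
Log ratio of the precipitates (horizontal axis, deposited log units, positive on the B52-probe side) of each named probe on the 4 arrays; colours mark the replicates, symbols the dye orientation and bars the mean of 2 replicates. B52 probe 13309 lies between 0.41 and 0.51 on every array, while the other 4 B52 probes spread over both sides of 0.

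The 5 probes for B52 did not run together on the turned arrays. Probe 832 lay at 0.13 ± 0.04, probe 2144 at 0.11 ± 0.08, probe 2736 at 0.03 ± 0.13 and probe 4048 at -0.33 ± 0.39 (SD, n = 2), and each of these 4 changed sign between arrays. The last value rested on 1 array of replicate 2, at -1.05, with the other 3 between -0.16 and 0.04, and without that array the mean was -0.10. Probe 832 lay between 0.0055 and 0.256 when 1 array was left out, lowest without replicate 1 with B52 RNA in Cy5 and highest without replicate 1 with B52 RNA in Cy3; probes 2144 and 2736 lay between -0.0632 and 0.279 and between -0.0972 and 0.157, lowest and highest without the same arrays. With 1 array left out, its replicate holds a single dye orientation, so dye and comparison are no longer separated in its mean. This holds for every value below with 1 array left out. Without turning, probes 832, 2144 and 2736 lay at -0.18, -0.17 and -0.14, with probe 832 below 0 on all 4 arrays. Probe 4048 then lay at -0.18 and probe 13309 at -0.012. In assembly Release 6 the B52 gene, CG10851, lies on chromosome arm 3R from 13661311 to 13666891, and pen-2, CG33198, on 2R from 18277439 to 18278762. Where in the B52 transcript each probe lies was not analysed here.

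By size, 20 probes stood at least 0.301 log units from 0 in 1 direction on all 4 arrays, a distance that is 2-fold on a log10 reading and 1.23-fold on a log2 reading. The rule had been set as 2-fold for log2 values, a distance of 1 log unit, which 0 and 0 probes met; the log10 reading was chosen after the values were seen. The 6 on the B52-probe side were CG15784, B52, Arc1, RpL36A, the ribosomal protein gene RpL23 and 1 probe without a gene. The 14 on the opposite side were pen-2, speck, Hsp70Ba, e, Mis12, CG3348, CG42807, the glutamine synthetase gene Gs2, the chaperone gene DnaJ-1, CG7924, the transcription elongation factor gene spt4, the juvenile hormone binding gene Jhbp2, CG9689 and 1 probe without a gene. With the sign pattern of a dye effect in place of the comparison, 6 and 34 probes met this rule, of which 6 and 1 had a single gene symbol. The replicate pattern gave 0 and 2 probes, neither with a single gene symbol, and the interaction 0 and 0. On the 2 arrays of replicate 2 alone, 80 and 192 probes met the rule, and on those of replicate 1 alone 18 and 23. With the arrays scaled to a common median absolute deviation, 2 and 5 probes met it.

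Across all 13963 probes, limma on the replicate means called 0 probes on either side at an adjusted p under 0.05. An unadjusted p under 0.05 was reached by 1808 probes, where chance gives 698, with 729 on the B52-probe side and 1079 on the opposite side. In the same test the dye pattern gave 1388 such probes, the replicate pattern 152 and the interaction 120. An excess over 698 was thus not particular to the comparison. For the comparison the number was 676 without the array of replicate 1 with B52 RNA in Cy5 and 1024 without the one with B52 RNA in Cy3. Only pen-2 passed in limma with robust moderation, at an adjusted p of 0.0403, and with genes tested in place of probes, at 0.0122. With the replicate number as a random block over the 4 arrays, 118 probes on the B52-probe side and 329 on the opposite side passed in limma. B52 probe 13309 had an adjusted p of 0.02 in that fit and pen-2 one of 0.0043. The fit took a correlation of -0.66 between the arrays of a replicate, which makes standard errors smaller than for separate arrays. With the 4 arrays as separate samples, 0 and 0 probes passed. On simulated data the random block made 69 false calls while it recovered 64 of 100 probes changed by 0.3 and 93 of 100 changed by 0.6. Without turning the arrays, 34 and 58 probes passed, and B52 probe 13309 lay at -0.01.

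The replicates repeated in part. Their means correlated across probes, which are not independent replicates, at a Pearson r of 0.311 and a Spearman rho of 0.347, and 60.8% of probes had the same sign in both; without the array of replicate 1 with B52 RNA in Cy5, r was 0.0763, and it was at most 0.285 without any of the other 3. Between the replicates, turned arrays of the same dye orientation correlated at r = 0.266 for Cy5 and 0.258 for Cy3. Those of opposite orientation correlated at r = 0.014 and -0.115, so the agreement of single arrays lay within the orientations. The comparison took 22.6% of the mean square over the 4 arrays, the dye pattern 40.2%, the replicate pattern 24.9% and the interaction 12.3%. As deposited, the 2 dye orientations of replicate 1 correlated at r = 0.608 across probes, while those of replicate 2 correlated at r = -0.167. A ratio that turns with the dye gives a negative r.

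**Figure D2:**
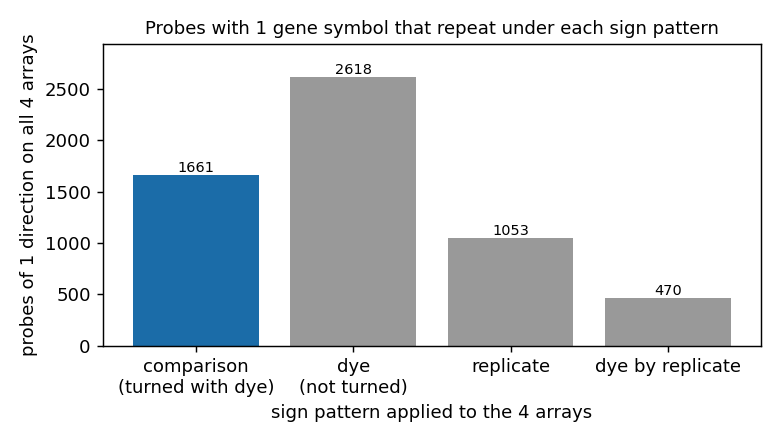
Number of probes with 1 gene symbol that kept 1 direction on all 4 arrays (vertical axis) under each of 4 sign patterns of the arrays. The comparison gave 1661 probes, the dye pattern 2618, the replicate pattern 1053 and the interaction 470.

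As a group, genes of the protein synthesis machinery lay on the B52-probe side. Of 39 measured cytosolic ribosomal protein genes 34 did, with a median of 0.07 log units and an adjusted p of 3.8e-07 in limma's camera with a preset correlation of 0.01 (adjusted p = 0.732 with an estimated correlation). Without the array of replicate 2 with B52 RNA in Cy3 their median was 0.046. RpL36A, RpL23 at 0.35 ± 0.01, RpS28b at 0.33 ± 0.06 and RpL24-like at 0.31 ± 0.01 (SD, n = 2) were the members with the largest moderated statistics. Of 45 translation factor genes 40 lay on that side, with a median of 0.07 and an adjusted p of 3.8e-07 (adjusted p = 0.714 with an estimated correlation). They were led by eIF3g1, eIF2beta at 0.29 ± 0.01, the poly(A)-binding protein gene pAbp at 0.19 ± 0.09 and eIF5B at 0.18 ± 0.09. Over all genes no member of any list passed, while adjusted over the list alone 6 ribosomal protein genes and the translation factor genes eIF3g1 and eIF2beta did. The median of the translation factors without the array of replicate 1 with B52 RNA in Cy5 was 0.042, at an adjusted p of 0.106 in camera. It was 0.108 and 0.0445 without the arrays with B52 RNA in Cy3 of replicates 1 and 2.

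Genes of oxidative phosphorylation, which make up the respiratory chain, were shifted the same way, with 53 of 74 on the B52-probe side, a median of 0.05 and an adjusted p of 0.000386 in camera (adjusted p = 0.714 with an estimated correlation). Among them the complex I subunit genes ND-PDSW and ND-MNLL lay at 0.23 ± 0.04 and 0.30 ± 0.18 and COX7A at 0.20 ± 0.03, whereas ND-B12, also of complex I, lay at -0.26 ± 0.14 (SD, n = 2). None passed adjusted over the list alone. The markers of hemocytes, the blood cells of the larva, were shifted too, with 17 of 23 on the B52-probe side, a median of 0.07 and an adjusted p of 0.0106 (adjusted p = 0.714 with an estimated correlation). The phagocytosis receptor gene eater lay at 0.31 ± 0.14, the prophenoloxidase gene PPO2 at 0.23 ± 0.04 and SPARC at 0.21 ± 0.05, but the laminin gene LanA at -0.18 ± 0.04, and these 4 passed adjusted over the list alone.

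Of the cuticle and epidermis genes, 58 of 99 lay on the B52-probe side, with a median of 0.02 and an adjusted p of 0.0178 (adjusted p = 0.714 with an estimated correlation). The larval cuticle genes Lcp9 at 0.27 ± 0.05 and Lcp65Ac at 0.21 ± 0.09, with Cpr56F at 0.21 ± 0.02 and Ccp84Ad at 0.26 ± 0.15 (SD, n = 2), had its largest moderated statistics, and none passed adjusted over the list alone. Without the array of replicate 1 with B52 RNA in Cy5, the median was 0.0233 for oxidative phosphorylation (adjusted p = 0.375 in camera) and 0.0147 for cuticle, close to its value on all arrays (adjusted p = 0.385). Without the array of replicate 1 with B52 RNA in Cy3, the medians were 0.0952 for oxidative phosphorylation, 0.0425 for cuticle and 0.0325 for hemocytes, the last at an adjusted p of 0.212. Without that of replicate 2 they were 0.0274, 0.0245 and 0.0395, the last at an adjusted p of 0.103.

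On the opposite side lay genes of neural stem cells and of eye patterning. Of 44 genes of neurogenesis and neuroblasts 36 did, with a median of -0.12 and an adjusted p of 3.8e-07 in camera (adjusted p = 0.714 with an estimated correlation), and 15 passed adjusted over the list alone. They were led by the Notch target E(spl)m3-HLH at -0.37 ± 0.01, the zinc finger gene klu at -0.37 ± 0.11 and the Snail family genes sna at -0.27 ± 0.02 and wor at -0.25 ± 0.004 (SD, n = 2). Of 47 genes of retinal determination and eye patterning 33 lay on that side, with a median of -0.08 and an adjusted p of 0.00058 (adjusted p = 0.714 with an estimated correlation), and 6 passed adjusted over the list alone. Without the array of replicate 1 with B52 RNA in Cy5 their median was -0.0512. The phosphatase gene csw lay at -0.32 ± 0.13, the Iroquois genes ara and mirr at -0.24 ± 0.03 and -0.28 ± 0.12, and the proneural zinc finger gene sens at -0.20 ± 0.03.

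Markers of glia lay there as well, 16 of 19, with a median of -0.09 and an adjusted p of 5.56e-05 (adjusted p = 0.714 with an estimated correlation), and 6 passed adjusted over the list alone. Gs2 lay at -0.47 ± 0.09, the septate junction genes Gli and Nrx-IV at -0.36 ± 0.03 and -0.28 ± 0.01 and the glial homeobox gene repo at -0.20 ± 0.07 (SD, n = 2). All 7 tracheal genes had a negative mean, with a median of -0.14 and an adjusted p of 0.00394 (adjusted p = 0.714 with an estimated correlation), and 3 passed adjusted over the list alone. These were pio at -0.27 ± 0.12, the FGF receptor gene btl at -0.19 ± 0.01 and its ligand gene bnl at -0.16 ± 0.06, while Gasp lay at -0.10 ± 0.02. Without the array of replicate 1 with B52 RNA in Cy3, the tracheal median was -0.054, at an adjusted p of 0.321 in camera.

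None of these 9 lists thus passed with an estimated correlation between genes. With 2 replicates that setting rests on 1 residual degree of freedom, so hardly any list could pass and it cannot decide whether the lists were shifted. Tested on simulated data with genes drawn independently, that setting also missed a list shifted by 0.1 (adjusted p = 0.974), which the preset correlation called (adjusted p = 1.45e-08). The directional test of fry, which does not compare a list with other genes, gave adjusted p values between 0.28 and 0.326 for the 9 lists. Without turning the arrays, none of these 9 lists was called, and mitochondrial ribosomal proteins and gut enzymes were, with medians of -0.06 and -0.08 and an adjusted p of 0.00449 each.

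**Figure D3:**
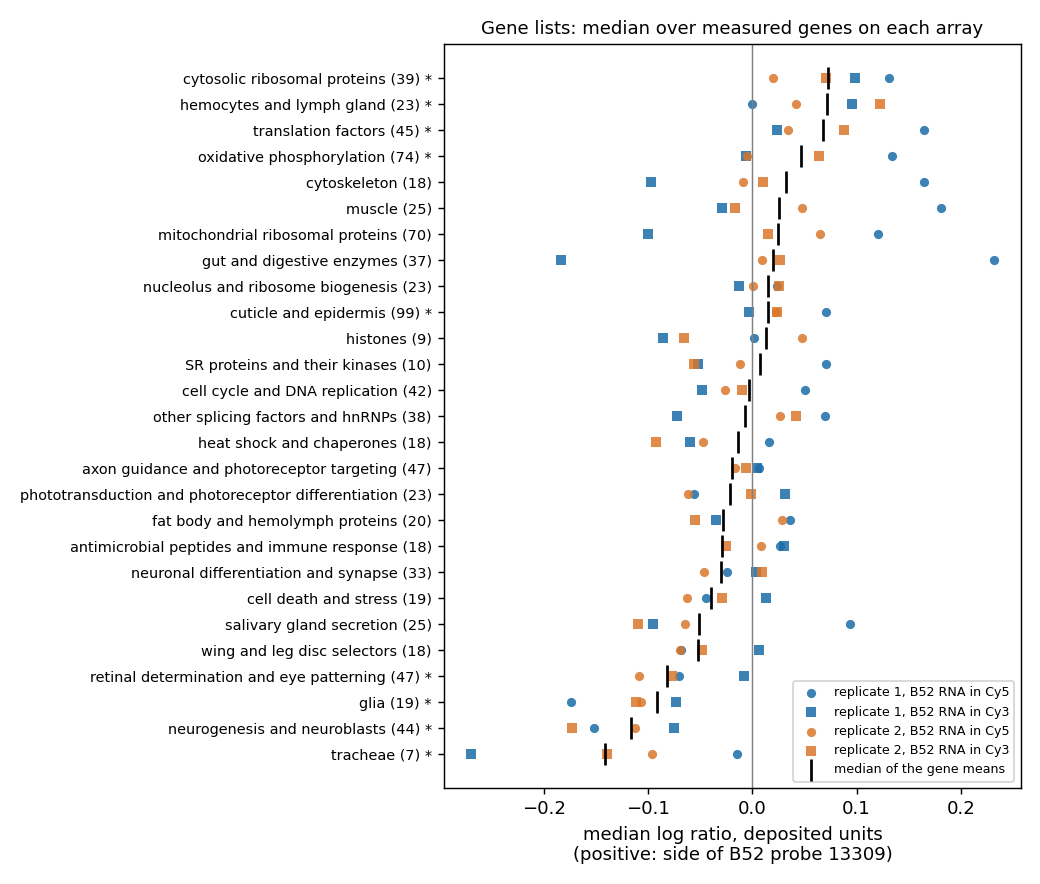
Median log ratio (horizontal axis, deposited log units, positive on the B52-probe side) of 27 gene lists on each of the 4 arrays, with the number of measured genes in parentheses and a star for an adjusted p under 0.05 in camera with the preset correlation; bars are the median of the gene means. Neurogenesis and glia lie below 0 on all 4 arrays, while cytosolic ribosomal proteins and translation factors lie above 0 on all 4.

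Genes of the splicing machinery did not pass as groups. The 10 SR protein and kinase genes had a median of 0.01 (adjusted p = 0.713 in camera), with Rsf1 at -0.12 ± 0.06, tra at 0.24 ± 0.34 and tra2 at -0.09 ± 0.003 (SD, n = 2). The 38 other splicing factor and hnRNP genes had a median of -0.01 and a mean of 0.002 (adjusted p = 0.606), with SmD3 at 0.20 ± 0.01, U2af50 at 0.21 ± 0.09 and SmD2 at 0.18 ± 0.04 against fne at -0.20 ± 0.10. Phototransduction and photoreceptor genes had a median of -0.02 (23 genes, adjusted p = 0.241), axon guidance and photoreceptor targeting genes -0.02 (47 genes, adjusted p = 0.598) and neuronal differentiation and synapse genes -0.03 (33 genes, adjusted p = 0.435). Within them, the carotenoid enzyme gene ninaB lay at -0.30 ± 0.15, the receptor gene drl at -0.33 ± 0.04 and the tyrosine hydroxylase gene ple at -0.25 ± 0.08, and of these 3 lists only drl passed adjusted over the list alone.

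Lists of several other tissues in the dissected front ends, unlike those of glia, tracheae, hemocytes and cuticle, did not pass with the preset correlation, and with an estimated correlation those 4 did not pass either (adjusted p = 0.714 each). The medians were 0.03 for muscle (25 genes, adjusted p = 0.0729 in camera), 0.02 for gut (37 genes, adjusted p = 0.0945), -0.05 for salivary gland secretion (25 genes, adjusted p = 0.136), -0.05 for wing and leg disc selectors (18 genes, adjusted p = 0.0729) and -0.03 for fat body and hemolymph proteins (20 genes, adjusted p = 0.606). Among them the muscle LIM gene Mlp84B lay at 0.31 ± 0.01 and the wing selector gene ap at -0.26 ± 0.04 (SD, n = 2). Mitochondrial ribosomal proteins had a median of 0.02 (70 genes, adjusted p = 0.0729), the cytoskeleton 0.03 (18 genes, adjusted p = 0.164), nucleolus and ribosome biogenesis 0.02 (23 genes, adjusted p = 0.327) and cell cycle and DNA replication -0.003 (42 genes, adjusted p = 0.606).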

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

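The tests of print position, spots without a gene, column reading, brain share and transgene RNA in this part were chosen only after the results they bear on were seen.

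The probe for e had 3 arrays between -0.63 and -0.62 and 1, replicate 1 with B52 RNA in Cy3, at -0.54, so that the gap took 0.877 of its range. Of 35 items examined in this way 1 stood out, and chance gives about 1 in 20.

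The 2 dye orientations of replicate 1 ran together as deposited, at r = 0.608 across probes, where a ratio that turns with the dye gives a negative r. The values argue against a trend over neighbouring spots as the whole cause, since r was 0.412 with the local medians removed. The local medians themselves correlated at r = 0.879. Local medians do not take out a pattern of single spots that recurs from block to block. On these 2 arrays, values at the same place of successive blocks correlated at r = 0.311 and 0.308 before the removal. Spots without a gene are argued against as the whole cause, since r was 0.572 over probes with a single gene symbol. Local medians and spots without a gene were not removed together, so both at once were not tested. That the columns already hold precipitate over precipitate cannot be told apart from a strong dye effect. Of 24 probes with a gene at the rule of size, B52 probe 13309 left out because the turning was chosen from it, 29.2% met it unturned (7 against 17, two-sided exact binomial p = 0.0639). That test takes probes as independent, which probes of the same arrays are not. Other counts over probes with a single gene symbol went the other way. In limma on these probes alone, 169 passed unturned and 1 turned. Those of 1 direction on every array numbered 2618 unturned and 1661 turned. Over all probes 40 met the rule unturned, of which 7 had a single gene symbol, and 20 turned, B52 probe 13309 included. Of the other B52 probes, 832, 2144 and 2736 lay farther from 0 unturned than turned, and 4048 nearer. If the columns are not to be turned, the shifts of the 9 lists may be dye effects; 9 lists were called with turning and 2 without. No biological explanation was tested for this pattern, as dye orientation is not a group.

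In camera with the preset correlation 9 gene lists were called, with protein synthesis on the B52-probe side and neurogenesis, glia and eye patterning on the other. None passed with an estimated correlation (adjusted p between 0.714 and 0.732), a setting that cannot decide with 1 residual degree of freedom. A trend over neighbouring spots is argued against as the whole cause of the calls, as 9 of 9 lists kept direction and call under the preset correlation with the local medians removed. If the columns hold a fixed dye ratio, a dye effect of equal size in both orientations cancels from the mean of a replicate. One of unequal size was not tested. If the columns already hold precipitate over precipitate, the turned means measure the dye pattern, so a dye effect stays open as the cause. A different share of brain tissue in the pools stays open. Of the 3 lists of brain cells 2 were called on the opposite side, neurogenesis at a median of -0.12 and glia at -0.09. Both were among the 9 lists that prompted the question, so their calls do not test it. The neuronal list, at -0.03 (adjusted p = 0.435 in camera), was not called. Also open, untested, are binding by GFP-B52, higher in its precipitate on the B52-probe side with Cy3 over Cy5 and on the opposite side with Cy5 over Cy3, and a difference in RNA abundance between the larvae, for which input RNA was not analysed here.

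A single B52 probe, 13309, lay far from 0 on all 4 arrays; as the turning was chosen from it, its single direction is not independent evidence. A trend over neighbouring spots is argued against, as the probe stayed at 0.48 log units with the local medians removed. RNA of the transgene itself stays open as a cause. That 1 of the 5 B52 probes met the rule of size is the observation itself, so this count cannot test it. Whether the other 4 lie inside the transgene was not analysed here. RNA of the transgene thus cannot be told apart from binding of the B52 transcript by its own protein. Each needs the probe to be higher in the GFP-B52 precipitate, and which precipitate was higher is unknown. If it was the GFP-NLS precipitate, neither applies.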

How the results depend on the processing

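The removal of print position, the restriction to probes with a single gene symbol and the log10 reading of the size rule were chosen only after the data were seen. Every alternative rests on the same 2 replicates; signal over background was not analysed here, and the cause of the changes was not tested except where the setting itself gives it. Without centring, 33 of 33 named probes and lists kept direction and side of the threshold, as they did with scaled arrays and with at least 1 array per replicate; the share of the mean square was 22.6% without centring. With arrays scaled to a common spread the share was 27.7%, 1019 probes reached an unadjusted p under 0.05, and 2 and 5 met the rule of size. With at least 1 array per replicate, r of the replicate means was 0.229.

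Leaving out 1 replicate or 1 array left fewer samples. Without 1 array, its replicate also held a single dye orientation, so changes there may come from dye as well as from the lost array. Probes at the rule of size then numbered between 6 and 80 on the B52-probe side and between 15 and 192 on the opposite side, unadjusted p under 0.05 between 676 and 1609, lists on the B52-probe side between 2 and 8, and r between 0.0763 and 0.285. B52 probe 2736 lay between -0.0972 and 0.157, B52 probe 2144 between -0.0632 and 0.279 and B52 probe 832 between 0.0055 and 0.256, all lowest without the array of replicate 1 with B52 RNA in Cy5; probe 2736 lay at -0.0615 without replicate 2. Without a replicate no residual degrees of freedom remain, so the probe and list tests have no value there.

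With 4 arrays as separate samples 955 probes reached an unadjusted p under 0.05 and 1036 with a dye term, and none passed. The random block, with a correlation of -0.66 within replicates, gave 118 and 329 probes and 2811 at an unadjusted p under 0.05. In limma with robust moderation, with genes in place of probes and with probes of a single gene symbol, 1 passed on the opposite side, pen-2; over the latter probes r was 0.394 and the share 24.7%. With print position removed r was 0.337, the share 29.0% and B52 probe 2736 lay at -0.005.

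Without turning, 34 probes passed on the positive and 58 on the negative side, and 34 met the rule of size on the negative side. Lists called numbered 0 and 2, r was 0.270 and the share 40.2%. With probes of a single gene symbol alone, 169 passed in limma without turning. If the columns hold a fixed dye ratio these values measure the dye pattern, and otherwise the comparison: B52 probes 832, 2144, 2736 and 13309 lay at -0.18, -0.17, -0.14 and -0.012, CG15784 at -0.0215, Listericin at -0.11, CG7912 at -0.16, GstD7 at -0.039, eIF3g1 at -0.0187, RpL36A at -0.029, pen-2 at 0.10, speck at 0.0395, Hsp70Ba at 0.0177, e at 0.0195 and CG3348 at 0.0032. With turning, B52 probes 832, 2144 and 2736 had lain nearer to 0, at 0.13, 0.11 and 0.03. The other probes that changed sign lay nearer to 0 without turning. So did those that kept their sign, with CG13561 at 0.10, Arc1 at 0.05, CG7916 at 0.003, CG4151 at -0.0003, Mis12 at -0.02, CecB at -0.09, MCPH1 at -0.06, ng1 at -0.07 and B52 probe 4048 at -0.18. The list medians were -0.011 for ribosomal proteins, 0.0159 for neurogenesis, 0.036 for glia, 0.0183 for eye patterning and -0.0125 for cuticle, and, without a change of sign, 0.0085 for translation factors, 0.005 for oxidative phosphorylation, 0.043 for hemocytes and -0.04 for tracheae. The rule of size at 1.5-fold and 3-fold on a log10 reading gave 39 and 107, and 0 and 4 probes; at 2-fold on a log2 reading, as designed, it gave 0 and 0. With an estimated correlation, and with fry, 0 and 0 lists were called. The planned relation to intron number and transcript length was not run.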

Other observations

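The test of neighbouring genes in this part was fixed before its result was seen, and all other values here were picked out after the results were seen.

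Immune genes went both ways. Of 18 immune genes 6 passed adjusted over the list alone, although none did over all genes and the list as a whole had an adjusted p of 0.898 in camera, with a median of -0.03, a mean of -0.01 and a test that pointed to the B52-probe side. The antifungal peptide gene Drs lay at 0.37 ± 0.03 and the peptidoglycan recognition gene PGRP-SC2 at 0.23 ± 0.0004, whereas CecB lay at -0.57 ± 0.20 and AttB at -0.34 ± 0.04 (SD, n = 2), each in 1 direction on all 4 arrays. In the salivary gland list, 12 of 25 genes passed adjusted over the list alone. Of all 25, 9 lay on the opposite side and 3 on the B52-probe side in 1 direction on all 4 arrays. The ecdysone-induced genes Eig71Eg at -0.40 ± 0.15, Eig71Ee at -0.30 ± 0.07 and Eig71Ei at -0.28 ± 0.03, with the glue gene ng2 at -0.53 ± 0.33, led it.

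Chaperone and stress genes showed single members far from 0 without a shift of their lists (medians of -0.01 over 18 genes, adjusted p = 0.44 in camera, and -0.04 over 19 genes, adjusted p = 0.44). Hsp70Ba lay at -0.62, but its close paralogs did not: Hsp70Bb lay at -0.01, Hsp70Bc at 0.06 and Hsp70Ab at 0.10. DnaJ-1 lay at -0.46 ± 0.14 and the endoplasmic reticulum chaperone gene Hsc70-3 at -0.25 ± 0.05, against Hsc70-4 at 0.18 ± 0.05 (SD, n = 2). The JNK phosphatase gene puc lay at -0.29 ± 0.04. Of 9 histone genes, whose list had a median of 0.01, a mean of -0.04 and an adjusted p of 0.819, the variant genes His2Av and His3.3B lay at -0.32 ± 0.04 and -0.38 ± 0.14.

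The enzymes of catecholamine metabolism e, speck and ple all lay on the opposite side, at -0.60, -0.63 and -0.25. No list of such genes had been fixed, so this grouping was not tested. The gene gl, whose protein Glass acts on the GMR enhancer, lay at 0.08 ± 0.18.

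One hypothesis was that part of the repeating probes comes from stock differences, which would give genes near each other on a chromosome (a difference of genetic background between the parents of the larvae). Among 200 genes, the 100 of each side that repeated best, 9 pairs were next neighbours, where random gene sets gave a mean of 3.72 (one-sided permutation p = 0.0115), so neighbours were more frequent than in random sets. Only 5 of the 9 pairs lay on the same side, among them members of gene families that lie side by side, such as CG8997 with CG7916, CG7916 with CG7953, Jhbp2 with Jhbp1 and Eig71Ed with Eig71Ee. Shared regulation of such families, or probes that cross-hybridise within them, may give the same count, and these were not tested apart.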
